A study of Mus musculus with 3 samples.

How the data were processed

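Single-nucleus RNA sequencing was applied to whole mouse hearts at embryonic day 9.5. Hearts of 3 genotypes of Ncx1, the alias of Slc8a1, were used: wild type (Ncx1+/+), heterozygous (Ncx1+/-) and homozygous mutant (Ncx1-/-). Per the labels' protocols, frozen hearts were homogenised mechanically, nuclei were sorted by flow cytometry for quality, and libraries were made with the 10x Genomics reagent kit version 3.1. Per the series design in the labels, 5 hearts were pooled for each genotype and 1 library was made from each pool.

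The values deposited by the authors are whole-number counts of unique molecular identifiers (UMIs) per gene and barcode, without normalisation. Per the submitters' processing notes, Cell Ranger 6.1.0 and the mouse build mm10 were used, whereas per the file headers the count tables were written by version 9.0.0 of that program. Whether intronic reads were counted is not given in the sources used here. Of the 27998 gene identifiers, 27645 (98.7%) matched the GENCODE M21 annotation of the same build, which was used for coordinates.

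Barcodes with at least 500 detected genes and at most 5% mitochondrial UMIs were kept. Doublets were scored in each library with Scrublet, and the highest-scoring nuclei were removed, down to the score that marks the top 8% and with ties at that score included, because its automatic threshold called 0 doublets in Ncx1-/- and 11.4% and 14.3% of nuclei in the other libraries. This removed 1097 of 13562, 1039 of 12305 and 1093 of 12325 nuclei. Counts were scaled to 10000 per nucleus, log-transformed and reduced to 30 principal components of 2000 variable genes. Nuclei were clustered by the Leiden method at resolution 1.0 on 15 nearest neighbours, with no correction between libraries. Clusters were named from fixed marker lists: a class needed a marker score of 0.42 and at least 3 markers detected in 10% of the nuclei at 20% of their highest level. A cluster with a median UMI count under 0.35 of the overall median stayed unnamed. Clusters with a doublet score over 0.15 were held out too. A cluster that scored highest for cushion mesenchyme joined the endocardial lineage if it carried at least 7 endothelial markers, and otherwise stayed unnamed, as cluster 17 did. The endocardial lineage was clustered again. Sub-clusters with at least 5 cushion mesenchyme markers 1.5 times above the rest of the lineage were set apart as mesenchyme-type, and those with 8 or more markers of another class were set aside as mixed. The remaining sub-clusters form the endocardial class, which includes vascular endothelium.

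Raw counts were summed over the nuclei of each class and library and scaled by the class total to CPM. A gene was measured in a class with at least 100 counts over the 3 libraries. A gene stood apart in a library where its CPM was at least 1.5 times higher, or lower, than in both other libraries and the 95% exact counting interval of each ratio excluded 1. Named genes are the 10 highest and 10 lowest in Ncx1-/- per class, ranked by the smaller of both ratios, and the 5 highest and 5 lowest in Ncx1+/-. Predicted genes, ribosomal, mitochondrial, haemoglobin and sex-linked genes were left out of the ranking. Members of the fixed lists that stood apart could also be named, or the 2 members with the most counts where no member did. A set of 13 genes was always reported in the endocardial class if measured.

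The 25 gene lists were cilia, hedgehog signalling, flow-responsive genes, mechanosensors, Notch signalling, endothelial-to-mesenchymal transition (EndoMT), BMP and TGF-beta signalling, cushion matrix, VEGF and angiogenesis, trabeculation, sarcomere, calcium handling, cardiac ion channels and conduction, calcium stress response, hypoxia and glycolysis, oxidative phosphorylation, cell cycle, p53 and apoptosis, integrated stress response, YAP and SRF targets, retinoic acid, haemoglobin, mitochondrial RNA, ribosomal protein and sex-linked genes. The markers of a class were left out of the lists in that class. In the endocardial class these were the endothelial markers only. The cushion mesenchyme markers, which set the mesenchyme-type sub-clusters apart from it, stayed in its lists. Each list was summarised by its members standing apart and by its median log2 ratio, which is to Ncx1+/+ unless Ncx1+/- is named. The percentile of that median among 10000 random lists of the same size, matched on mean CPM in 40 bins, describes these libraries and is not a test of the genotypes. Counting intervals of medians came from 1000 Poisson resamples.

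With 1 library per genotype no test between genotypes is possible, and no value has a replicate check. Intervals are exact Poisson or exact binomial (Clopper-Pearson) intervals at 95% and cover counting error only. Folds against a level of 0 use a floor of 3 counts over the class.

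The calling rule was tested on simulated counts drawn from the real means and library sizes, with 200 genes changed by known folds. In the endocardial class (10751 genes tested) it called 94.0% of genes doubled and 98.0% of genes set to 0.5 of their level, and 27 of 10554 unchanged genes (0.256%). In the cardiomyocytes (13612 genes) these shares were 100% and 98.0%, with 8 of 13413 unchanged genes (0.0596%). In the mesenchyme-type sub-clusters (6710 genes) they were 98.0% and 80.9%, with 42 of 6517 (0.644%). A further 50 draws with no gene changed gave the calls expected in each library. The simulations hold counting error and no variation between pools.

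Sample groups, marker lists, gene lists, the rule for named genes, the comparisons and most alternatives were fixed before the data were examined. The doublet rule, the thresholds for naming clusters and sub-clusters, the holding out of a pair of cardiomyocyte clusters and the choice of list medians treated as leading results were set afterwards. The alternatives fixed then were at least 1000 detected genes, no doublet filter, scaling of each gene within its library before clustering, Leiden resolutions 0.5 and 2.0, TMM factors from edgeR, median-of-ratios size factors, no count minimum or 300 counts, mean CPM over nuclei, nuclei thinned to 2000 UMIs, and a threshold of 2 times. Alternatives added after seeing the data were the automatic Scrublet thresholds, totals without Slc8a1 and Malat1, the endocardial lineage as 1 class, all cardiomyocyte clusters, cardiomyocyte free RNA subtracted, the endocardial class without sub-cluster 12, sub-clustering without the genes standing apart in Ncx1-/-, and unnamed cluster 17 counted as mesenchyme-type. For 1 test the lineage nuclei thinned to 2000 UMIs were sub-clustered again and named by the same rule. The epicardial comparison was not run, because Ncx1+/- held 26 such nuclei and at least 50 were required. Some items are not reported here.

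Tools were Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5 with its version of Scrublet, anndata 0.12.19, igraph 0.11.9, scikit-learn 1.9.0, matplotlib 3.10.9, R 4.3.3 and edgeR 4.0.16.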

Results

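Nuclei of whole embryonic mouse hearts were profiled at embryonic day 9.5, when endocardial cells of the atrioventricular canal and outflow tract begin to form cushion mesenchyme. The libraries compare 3 genotypes of Ncx1, a sodium-calcium exchanger of the heart muscle membrane, with 1 library from 5 pooled hearts for each. Embryos without this exchanger lack a regular heartbeat and blood flow, and the series title places the data in a study of primary cilia, blood flow and endothelial-to-mesenchymal transition (EndoMT). The Ncx1+/+, Ncx1+/- and Ncx1-/- tables held 13805, 12563 and 12525 barcodes with 59898298, 49022310 and 52985283 UMIs. After filtering, 12465, 11266 and 11232 nuclei remained. Median UMIs per deposited barcode were 3863, 3460 and 3665. Values for the 3 libraries are given in this order throughout.

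Slc8a1 (ENSMUSG00000054640), the gene of the exchanger, lies on the minus strand of chromosome 17 from 81373105 to 81738377 in mm10. Over all nuclei it stood at 11828, 6540 and 1033 CPM, so the level in Ncx1+/- was 55.3% of that in Ncx1+/+ and the level in Ncx1-/- was 8.74% (counting interval 8.65 to 8.82%). In cardiomyocytes it stood at 16655, 8785 and 1297 CPM, and the Ncx1-/- level was 7.79% of wild type. In endocardial nuclei the levels were 197, 101 and 15.2 CPM, in the mesenchyme-type sub-clusters 230, 154 and 27.0 CPM, and in epicardial nuclei 2894, 2223 and 216 CPM. In erythroid nuclei they were 547, 221 and 315 CPM. Levels in endocardial and mesenchyme-type nuclei are no separate support for the genotype labels, because cardiomyocyte RNA reaches these nuclei. In the endocardial class cardiomyocyte markers stood at 8.94, 10.1 and 12.6% of their level in cardiomyocytes. For Slc8a1 the endocardial level was a smaller share of the cardiomyocyte level, so the share of these markers need not hold for other genes. Such RNA was not measured in epicardial and erythroid nuclei, so their levels are not taken as support either. The erythroid level in Ncx1-/- was 57.5% of that in Ncx1+/+ (43.8 to 74.5%), and the cause was not tested. The deleted part of the gene is not given in the sources used here, so it is not known whether the reads left in Ncx1-/- lie outside it.

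**Figure D1:**
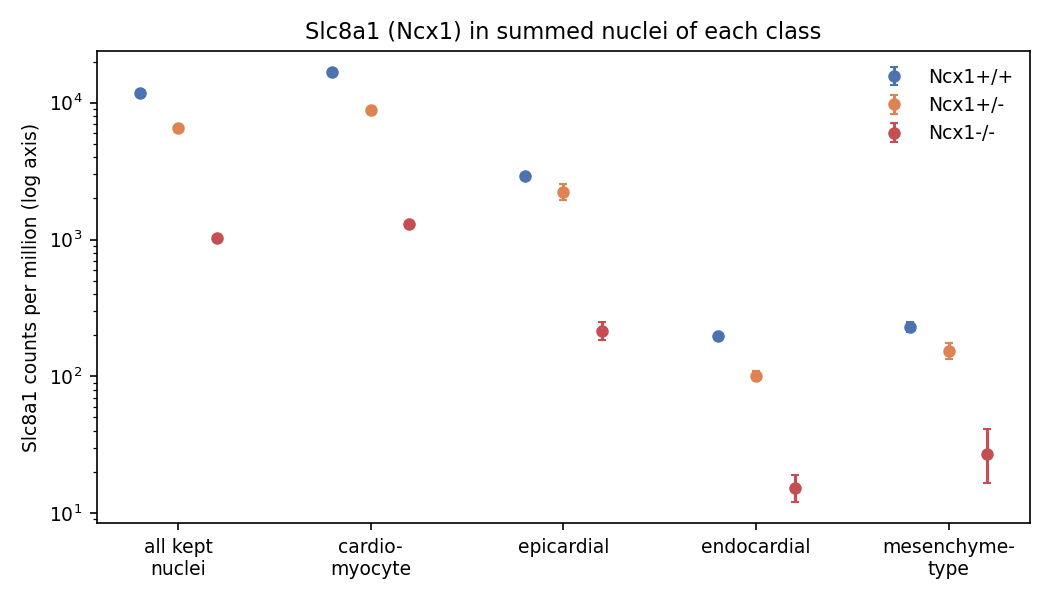
Slc8a1 in CPM (log axis), with 1 point per library and bars for the 95% exact counting interval. Summed nuclei are shown for all kept nuclei and for the cardiomyocyte, epicardial, endocardial and mesenchyme-type classes. Erythroid nuclei, at 547, 221 and 315 CPM, are not drawn. In cardiomyocytes the points lie at 16655, 8785 and 1297 CPM for Ncx1+/+, Ncx1+/- and Ncx1-/-.

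Cardiomyocytes were the most abundant class, with 65.6, 67.6 and 73.7% of kept nuclei. The endocardial lineage, marked by genes such as Tek, Emcn and Eng, made up 19.7% (exact binomial interval 19.0 to 20.4), 18.5% (17.8 to 19.2) and 14.0% (13.3 to 14.6). Erythroid nuclei, marked by haemoglobins, made up 3.97% (3.64 to 4.33), 4.13% (3.77 to 4.51) and 0.846% (0.685 to 1.03). Mesenchyme-type sub-clusters 0 and 5, with Sox9, Pdgfra and Twist2 among their leading genes within the lineage, held 487, 347 and 201 nuclei. This was 19.8% (18.2 to 21.4), 16.7% (15.1 to 18.3) and 12.8% (11.2 to 14.6) of the lineage. With the genes standing apart in Ncx1-/- left out of the sub-clustering, the shares were 26.3, 21.6 and 12.2%. The share in Ncx1-/- was 3.41% at Leiden resolution 2.0, 6.15% with at least 1000 genes detected and 8.54% without a doublet filter. Against nuclei outside the lineage, the endothelial marker Eng was among the leading genes of both of these sub-clusters, so they are compared by number. The share depends on cluster 17, which stayed unnamed and held 73, 37 and 198 nuclei. It carried 10 of 13 cushion mesenchyme markers, and each endothelial marker was lower in it than in the mesenchyme-type sub-clusters. Eng differed most, at 4.30 CPM against 641 CPM, while Flt1 stood at 205 against 325 CPM and Tek at 126 against 868 CPM. Cluster 17 had Sox9 at 4.30 against 177 CPM and Col1a1 at 243 against 0.894 CPM. Of the epicardial list it also carried Lrp2, at 378 against 1.79 CPM. Podxl, Bnc1, Wt1 and Upk3b of that list stood at 295, 70.5, 65.4 and 64.5 CPM against 26.8, 0, 0.671 and 0.224 CPM. Tbx18, Tcf21 and Itga4 of that list were lower in cluster 17, at 0, 11.2 and 6.88 CPM against 0.671, 16.8 and 98.1 CPM. The epithelial genes Wnt6, Grhl2 and Epcam stood at 97.2, 68.0 and 48.2 CPM in cluster 17. All of these are fixed markers singled out after their values were seen. With cluster 17 counted as mesenchyme-type the shares were 22.1, 18.1 and 22.6% of the lineage, so the order of the genotypes rests on leaving it out. Epicardial nuclei numbered 176, 26 and 225, and megakaryocytes 29, 12 and 2. Cardiomyocyte clusters 3 and 6, each led by a marker of another class, were held out of the comparisons. Cluster 3 took 4.65, 4.85 and 8.11% of kept nuclei and cluster 6 took 8.56, 8.23 and 3.65%. Unnamed clusters took 8.09, 8.49 and 8.44%: beside cluster 17 these were cluster 10, led by heat-shock and mitochondrial genes, with 391, 427 and 277 nuclei, cluster 15 with 535, 431 and 330, and cluster 19 with 10, 62 and 143. Mixed sub-clusters of the lineage took 0.971, 0.914 and 1.01%. Shares also depend on dissection and on the sorting of nuclei, and no test between pools was possible.

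The first comparison asks how endocardial and endothelial nuclei of hearts without the exchanger differ from those of both other genotypes. Genes of hypoxia and glycolysis were higher in Ncx1-/-: 30 of 32 measured list members stood apart upward and 0 downward, with a median log2 ratio of 1.83 to Ncx1+/+ (counting interval 1.75 to 1.88) and 1.32 to Ncx1+/-. Slc2a1, a glucose transporter of the plasma membrane, stood at 44.5, 76.6 and 259 CPM, 5.81-fold higher than in Ncx1+/+ (5.22 to 6.47). Pdk1, the kinase that inhibits pyruvate dehydrogenase, stood at 37.1, 63.2 and 240 CPM (6.48-fold, 5.77 to 7.28), and Ldha, which converts pyruvate to lactate, at 151, 209 and 486 CPM. In the cushion matrix list 9 of 26 members were lower and 1 higher. Of the lower members, Vcan, the hyaluronan-binding proteoglycan versican, stood at 496, 373 and 130 CPM (3.82-fold lower, 3.53 to 4.14), and Col3a1, a fibrillar collagen, at 154, 128 and 22.3 CPM (6.92-fold lower, 5.75 to 8.41). Of 10760 measured genes, 809 were higher and 465 lower in Ncx1-/- than in both others. The share of higher genes was 63.5%, against 50.6% with TMM factors and 42.8% with median-of-ratios size factors, and the latter moved the median log2 ratio of all measured genes from 0.10 to -0.04.

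Among the genes furthest above both other libraries were Adm, the vasodilator peptide adrenomedullin, at 1.17, 2.36 and 16.7 CPM (14.2-fold over Ncx1+/+, 7.77 to 28.6), and Ankrd37, a hypoxia-inducible ankyrin repeat gene, at 2.94, 10.1 and 47.4 CPM (16.1-fold). Ddit4, an inhibitor of mTOR signalling, was 6.53-fold higher and Bhlhe40, a transcriptional repressor, 6.50-fold. Sparcl1, a matricellular protein gene, was 8.45-fold higher, Vldlr, a lipoprotein receptor, 7.66-fold, and Mt1, a metallothionein, 11.8-fold. Cacng3, which encodes an auxiliary subunit of glutamate receptors, was 8.91-fold higher, Tmem255a 6.27-fold and Grin2c, an NMDA receptor subunit, 6.23-fold. Other members of the hypoxia and glycolysis list were higher by 7.88-fold (Bnip3, a mitophagy receptor), 5.54-fold (Egln3, an oxygen-sensing hydroxylase), 4.06-fold (Hk2, a hexokinase) and 4.85-fold (Slc16a3, a lactate exporter). Fam155a was furthest below, at 155, 92.8 and 2.97 CPM, 52.0-fold lower than in Ncx1+/+ and 31.2-fold lower than in Ncx1+/-. Dkk2, a secreted modulator of Wnt signalling, stood at 25.4, 11.8 and 0.743 CPM, and Ano1, a calcium-activated chloride channel, at 44.7, 33.2 and 3.53 CPM. Syndig1 was 25.2-fold lower than in Ncx1+/+, the protocadherin gene Pcdh11x 20.4-fold and the sialyltransferase gene St6galnac5 13.5-fold. With 1 to 3 counts left in Ncx1-/-, the ratio to Ncx1+/+ was 0.0271 for the neuropeptide gene Nts (0.000677 to 0.156), 0.0350 for Pkhd1l1 (0.00713 to 0.104), 0.0575 for the calcium channel gene Cacna1b (0.00683 to 0.216) and 0.0876 for Rtn1 (0.0176 to 0.268). Several of the lower genes, such as Fam155a, Syndig1, Dkk2, Ano1 and Pkhd1l1, also led sub-clusters 8, 6 and 9, which held 401, 316 and 121 nuclei of Ncx1+/+ and 9, 2 and 4 of Ncx1-/-. Grin2c, Egln3 and Ankrd37 led sub-cluster 12, with 13, 113 and 557 nuclei, and a sub-cluster held mostly by 1 library can reflect that library rather than a cell type. Most endocardial nuclei of Ncx1+/+ lay in sub-clusters 2, 8, 6 and 4, and most of Ncx1-/- in 12, 10 and 7.

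In the EndoMT list, 8 of 33 measured members were lower in Ncx1-/- than in both others and 0 higher, and the median log2 ratio of -0.26 lay at percentile 0.09 of the random lists. That median was -0.13 without sub-cluster 12 and -0.16 at Leiden resolution 2.0, both inside the central 95% of the random lists matched to the full class (-0.18 to 0.12). Sox9, a transcription factor of cushion and cartilage cells, stood at 30.6, 20.5 and 6.69 CPM (4.58-fold lower than in Ncx1+/+), Tgfb2, a growth factor needed for cushion development, at 303, 287 and 143 CPM, and Tbx20, a T-box factor of the heart, at 1342, 1128 and 501 CPM. Twist2 was 3.19-fold lower, Cdh11 2.32-fold, Postn (periostin) 3.12-fold and Msx1 1.54-fold. Of these lower members, Sox9, Cdh11, Postn and Msx1 are also markers that set the mesenchyme-type sub-clusters apart. The same holds for Postn, Tnc and Col3a1 in the cushion matrix list. Members that did not stand apart include Snai1, at 6.17, 6.57 and 8.92 CPM with a ratio of 1.45 (0.973 to 2.14), and Twist1, at 22.9, 21.3 and 17.5 CPM. Snai2 was below 100 counts and not measured. The cushion matrix list had a median of -0.28 at percentile 0.02, and of -0.42 without sub-cluster 12. Tnc (tenascin C) stood at 61.3, 55.6 and 14.3 CPM, Fbln2 was 3.70-fold lower, Col5a1 3.41-fold, Col5a2 2.17-fold, the laminin chain gene Lama4 2.03-fold and Hapln1 1.56-fold. Adamts9, a protease that cleaves versican, was 1.84-fold higher.

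For the flow-responsive list the median log2 ratio was -0.00 at percentile 36.8, and 2 of 24 members were higher and 4 lower. Klf2, a transcription factor induced by shear stress, did not stand apart, at 193, 192 and 151 CPM with a ratio of 0.779 (0.717 to 0.846), whereas the related Klf4 was lower, at 19.6, 20.1 and 6.50 CPM with a ratio of 0.332 (0.225 to 0.478). Klf6 was 1.73-fold lower, Heg1, an endothelial receptor of the cerebral cavernous malformation pathway, 1.79-fold and Igfbp5 1.52-fold. The arterial genes Sox17, at 32.1, 40.8 and 132 CPM, and Gja4, at 30.4, 38.5 and 90.0 CPM, were higher. Nos3, the endothelial nitric oxide synthase, stood at 150, 153 and 160 CPM and Notch1 at 196, 169 and 153 CPM, neither standing apart. In the cilia list 3 of 51 members were higher and 1 lower. Its median of 0.07 lay at percentile 15.4 and turned to -0.01 with TMM factors and -0.07 with median-of-ratios size factors. The intraflagellar transport gene Ift88 stood at 44.0, 43.7 and 45.9 CPM, the ciliary GTPase gene Arl13b at 54.0, 54.8 and 48.1 CPM, the dynein heavy chain gene Dync2h1 at 122, 109 and 109 CPM, and Pkd2, the gene of polycystin-2, at 119, 107 and 105 CPM. None of these 4 stood apart. Ift20, Ift22 and Mks1 were 1.86-, 2.32- and 1.72-fold higher, and Wdr35 was 2.67-fold lower. In the hedgehog list, a pathway that signals through cilia, 3 of 11 members were lower and 0 higher, with a median of -0.39 at percentile 0.04: Gli2 was 4.27-fold lower, Gli3 1.83-fold and the co-receptor gene Boc 2.62-fold.

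**Figure D2:**
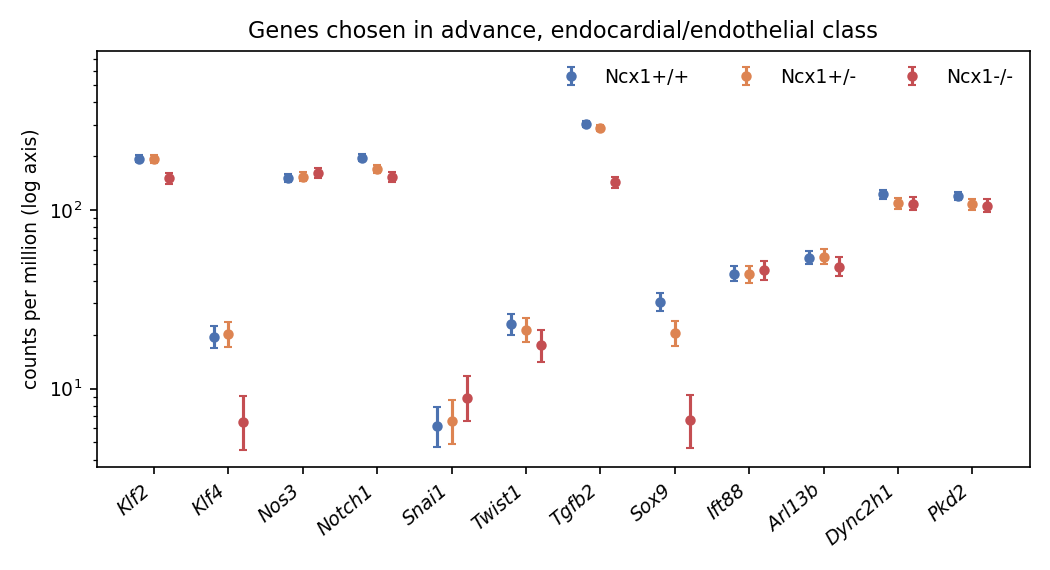
CPM (log axis) in the endocardial class for 12 genes of the set chosen in advance, with 1 point per library and bars for the 95% exact counting interval. Klf4, Tgfb2 and Sox9 lie lower in Ncx1-/-, at 6.50, 143 and 6.69 CPM, and the cilia genes Ift88, Arl13b, Dync2h1 and Pkd2 did not stand apart.

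Other lists in the endocardial class moved in both directions. In the VEGF and angiogenesis list (median 0.46, percentile 99.7) 5 of 15 members were higher, among them Vegfa (3.77-fold), Aplnr, the apelin receptor gene (5.52-fold), and Flt4 (1.82-fold), while the netrin receptor gene Unc5b was 1.74-fold lower. In the trabeculation list 0 of 22 members were higher and 5 lower (median -0.07, percentile 18.4). Nrg1, which encodes the neuregulin that signals from endocardium to muscle, stood at 2513, 2186 and 737 CPM, and Slit2 and Erbb3 were 2.99- and 6.67-fold lower. In the Notch list (median -0.03, percentile 18.8) the ligand gene Jag2 was 3.60-fold and Notch3 1.59-fold higher, and Hey2 was 1.98-fold lower, of 17 members. In the BMP and TGF-beta list (median 0.24, percentile 96.6, 18 members) Bmp2 was 1.70-fold and the receptor gene Acvrl1 2.90-fold higher, and Bmper, a BMP modulator gene, was 2.39-fold lower. Bmp2 stood at only 7.34, 7.88 and 12.5 CPM here, against 84.2, 83.9 and 46.8 CPM in cardiomyocytes. Free cardiomyocyte RNA may supply an unknown part of its levels in Ncx1+/+ and Ncx1+/-, so the Bmp2 fold is not exact. In Ncx1+/+ Slc8a1 stood at 197 CPM here against 16655 CPM in cardiomyocytes, a smaller share than that of the cardiomyocyte markers. In the mechanosensor list (median -0.15, percentile 10.3) Heg1 and Vcl, the vinculin gene, were lower of 13 members. In the retinoic acid list the median was -0.27 (percentile 0.525), although the 2 of 11 members that stood apart, Cyp26a1 at 5.85-fold and Nr2f2 at 2.69-fold, were higher. With no count minimum that median was 0.12.

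Lists of metabolism and RNA quality also differed. The ribosomal protein list had a median log2 ratio of 0.95 to Ncx1+/+ and 0.58 to Ncx1+/-, with 16 of 32 members higher. The mitochondrial RNA list had 0.66 and 0.06, with 1 of 12 members higher, and the oxidative phosphorylation list 0.60, with 4 of 36 members higher. Malat1, a nuclear noncoding RNA, took 4.68, 4.95 and 8.43% of the UMIs of kept nuclei, and median UMIs per endocardial nucleus were 4897, 4102 and 3533. Cardiomyocyte markers in endocardial nuclei stood at 8.94, 10.1 and 12.6% of their level in cardiomyocytes. Beside this, the sarcomere list had a median of 0.48, with Myh7, a myosin heavy chain gene, higher of 36 members. With cardiomyocyte free RNA subtracted, the Myh7 log2 ratio to Ncx1+/- turned to -0.27. This decides nothing, because Myh7 is among the cardiomyocyte markers that set the amount subtracted. The calcium handling list had a median of 0.24 (percentile 97.1), with 5 of 29 members higher and 2 lower. The haemoglobin list had a median of -0.99, with 5 of 5 members lower, next to the lower share of erythroid nuclei. The integrated stress list (0.34, percentile 93.3) had 3 of 16 members higher, and in the calcium stress list (0.40, percentile 94.1) Nr4a1, an immediate early gene, was lower of 14. Against Ncx1+/- the calcium stress median had the opposite sign, at -0.07 and percentile 3.03. For the cell cycle list (0.08, percentile 75.2) 0 of 49 members stood apart, and for the p53 and apoptosis list (0.06, percentile 26.1) 1 of 21, Aen. The ion channel list (0.03, percentile 26.8) had 1 of 9 members higher, and the list of YAP and SRF targets (-0.00, percentile 41.4) 1 of 24 higher and 3 lower. Against Ncx1+/- the median of the YAP and SRF targets was -0.13, at percentile 1.17. The medians of the cell cycle, p53 and ion channel lists turned below 0 with TMM factors and with median-of-ratios size factors, and the small medians of the flow-responsive list and of the YAP and SRF targets turned above 0 with totals that leave out Slc8a1 and Malat1.

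The next comparison concerns the mesenchyme-type sub-clusters 0 and 5, which carry cushion markers within the lineage. Here too hypoxia and glycolysis genes were higher in Ncx1-/-, with 20 of 25 members upward, 0 downward and a median log2 ratio of 1.49 to Ncx1+/+ (1.40 to 1.66) and 1.16 to Ncx1+/-. Pdk1 stood at 39.1, 47.1 and 189 CPM (4.84-fold, 3.69 to 6.37) and Hk2 at 120, 159 and 507 CPM, while Pgk1, Slc2a1 and Tpi1 were 4.09-, 4.15- and 3.47-fold higher. Postn was not detected in Ncx1-/-, at 58.6, 15.2 and 0 CPM, but stood at 74.2, 54.7 and 66.2 CPM with cluster 17 counted in, so its difference rests on leaving that cluster out. Robo2, a receptor for Slit ligands, stood at 737, 446 and 29.6 CPM, and Tnc at 250, 113 and 24.4 CPM. Vcan stood at 2051, 1360 and 640 CPM (3.20-fold lower), Sox9 at 203, 183 and 87.4 CPM (2.33-fold lower) and Twist1 at 102, 93.4 and 51.4 CPM (1.99-fold lower). Of 6708 genes measured without cluster 17, 329 were higher and 292 lower. The share higher was 52.98%, against 33.9% with median-of-ratios size factors, which moved the median of all measured genes from 0.04 to -0.10.

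Further genes higher in these sub-clusters were Tmem100, an endothelial membrane protein gene (7.59-fold), Dpp6 (7.06-fold), Plod2, a lysyl hydroxylase gene of collagen (3.32-fold), and Bsg, the basigin gene (3.32-fold). Tll1, a metalloprotease gene, was 3.79-fold higher, but its log2 ratio turned to -0.68 at Leiden resolution 2.0. Grid1, Pde3a and the exchanger gene Slc24a2 were 11.9-, 8.64- and 8.05-fold lower, Epha3, an ephrin receptor gene, 5.33-fold, Plxna4, a semaphorin co-receptor gene, 5.39-fold and Ablim3 4.15-fold. For Pde1a, with 2 counts in Ncx1-/-, the ratio was 0.0364 (0.00437 to 0.134). With cluster 17 counted in, 312 of the 621 genes stood apart in the same direction and 12 in the opposite one, the log2 ratio of Pde3a turned to 0.02, and those of Tnc, Plxna4 and Klf2 to Ncx1+/- turned to 0.60, 0.05 and -0.05. Robo2, Epha3 and Pde1a led sub-cluster 5, which held 323, 205 and 79 nuclei beside 164, 142 and 122 of sub-cluster 0. In the EndoMT list, without the markers that name the class, 1 of 27 members was higher and 3 lower (median -0.11, percentile 35.9). In the cushion matrix list 1 of 21 was higher and 5 lower (-0.15, percentile 18.2). The VEGF list had a median of 0.54, with Kdr, a VEGF receptor gene, 2.74-fold higher. Endothelial Cdh5, Klf2 and Nos3 were 2.03-, 1.88- and 2.10-fold higher, but with each gene scaled within its library before clustering the log2 ratio of Klf2 was -0.00. In the BMP and TGF-beta list (median -0.32, percentile 1.73) Bmp6 and Bmper were lower of 16 members. The cilia median was 0.13 at percentile 68.0 and -0.00 with median-of-ratios size factors, and Pkd1 was lower of 34 members. The ribosomal protein and sarcomere medians were 0.92 and 0.45, and cardiomyocyte markers stood at 10.4, 11.0 and 13.9% of their level in cardiomyocytes.

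In cardiomyocytes, the cells in which the exchanger is mainly used, 9 of 22 integrated stress response genes were higher in Ncx1-/- and 0 lower. The other 13 measured genes of the list did not stand apart. The list median was 0.86 to Ncx1+/+ (0.73 to 1.01) and 0.53 to Ncx1+/-. Slc7a3 and Slc7a11, amino acid transporter genes, were 12.5- and 3.23-fold higher, Trib3, a pseudokinase gene of this response, 22.0-fold (10.9 to 51.6) and Stc2, a secreted glycoprotein gene, 4.89-fold. Hypoxia and glycolysis genes were higher too, with 17 of 35 members upward, 0 downward and a median of 0.80 to Ncx1+/+ (0.77 to 0.87) and 0.57 to Ncx1+/-. Pdk1 stood at 169, 183 and 340 CPM, Vegfa at 140, 171 and 287 CPM, and Egln3 was 5.46-fold higher. The immediate early genes Egr1, at 5.32, 12.3 and 0.926 CPM, Fosb, at 8.86, 25.7 and 2.24 CPM, and Fos, at 44.5, 62.0 and 16.2 CPM, were lower. Of 13627 measured genes, 495 were higher and 387 lower in Ncx1-/- than in both others, 56.1% higher. The nuclei compared numbered 6529, 6147 and 6958, with median UMIs of 3757, 3436 and 3664.

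Also furthest above were Ndufa4l2, a hypoxia-inducible mitochondrial gene, at 1.36, 5.06 and 26.7 CPM (19.7-fold, 14.1 to 28.3), Car12, a carbonic anhydrase gene, at 1.77, 1.82 and 11.5 CPM, and Mt2, a metallothionein gene (13.5-fold). Espn, an actin-bundling protein gene, was 14.8-fold higher, Kbtbd11 13.3-fold, Slc30a10, a metal transporter gene, 12.3-fold and Prl8a2, a prolactin family gene, 4.15-fold. With 2 counts in Ncx1+/+, the ratio was 78.4 (21.4 to 653) for Sncb, the beta-synuclein gene, and 43.9 (11.8 to 368) for Chac1, a glutathione-degrading enzyme gene. The other lower genes were Muc13 (5.22-fold), Lhfpl3 (4.74-fold), Pik3c2g (3.92-fold), Lrrtm4 (3.86-fold), the retinaldehyde dehydrogenase gene Aldh1a3 (3.77-fold), Epha6 (3.74-fold), Ccdc63 (3.13-fold) and Slc22a4 (3.10-fold). Bmp2, a signal of the canal muscle, and Nrp2, a co-receptor for semaphorins and VEGF, were lower: Bmp2 stood at 84.2, 83.9 and 46.8 CPM and Nrp2 at 114, 116 and 51.4 CPM.

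Lists of contraction had medians between -0.03 and 0.13 in cardiomyocytes. In the calcium handling list the median was -0.03 (percentile 68.9) and turned to 0.02 with all cardiomyocyte clusters, with Itpr3 and S100a1 1.89- and 2.05-fold higher and the channel gene Cacna1d 1.64-fold lower, of 34 members. The ion channel list had a median of 0.00, and Gja5, the connexin 40 gene of fast conduction, was 1.88-fold higher of 20 members. The sarcomere median was 0.13 (percentile 99.9), and Lmod2, an actin filament regulator gene, was 1.64-fold lower of 29 members. In the calcium stress list (0.10, percentile 93.9) 4 of 18 members were lower, the genes Egr1, Fos, Fosb and Jun. The BMP and TGF-beta list (-0.22, percentile 0.29) had 1 of 24 members higher and 3 lower, the cushion matrix list (-0.22, percentile 0.225) 1 of 27 and 4, and the EndoMT list (-0.17, percentile 1.77) 0 of 34 and 4. In the hedgehog list (-0.26, percentile 1.90) Gli3 was lower of 11 members, in the mechanosensor list (-0.04, percentile 55.1) Piezo2 was 3.03-fold lower of 17, and among the YAP and SRF targets (-0.01, percentile 76.9) Cyr61 was 1.67-fold lower of 24. The cilia list (0.05, percentile 87.9) and the Notch list (-0.08, percentile 30.03) held 0 members standing apart, of 57 and 12, and the cell cycle list (-0.16, percentile 0.67) 0 of 49. In the p53 list (-0.02, percentile 43.5) Cdkn1a, Bbc3 and Sesn2 were higher of 23. In the flow-responsive list (-0.14, percentile 9.69) 2 of 19 members were higher, in the VEGF list (-0.13, percentile 13.9) 2 of 16 higher and 2 lower, in the trabeculation list (-0.04, percentile 52.3) 1 of 26 higher and 2 lower, and in the retinoic acid list (-0.17, percentile 11.8) 2 of 11 lower. The medians of the oxidative phosphorylation, ribosomal protein and mitochondrial lists were 0.11, 0.34 and 0.04, and haemoglobin stood at -1.11 with 5 of 6 members lower. The calcium handling, p53 and YAP medians turned above 0 under each of the 3 other scalings. Against Ncx1+/- the flow-responsive, cilia, mitochondrial and ribosomal protein medians were -0.27, 0.08, -0.26 and -0.02, at percentiles 0.06, 99.4, 0.32 and 91.95.

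**Figure D3:**
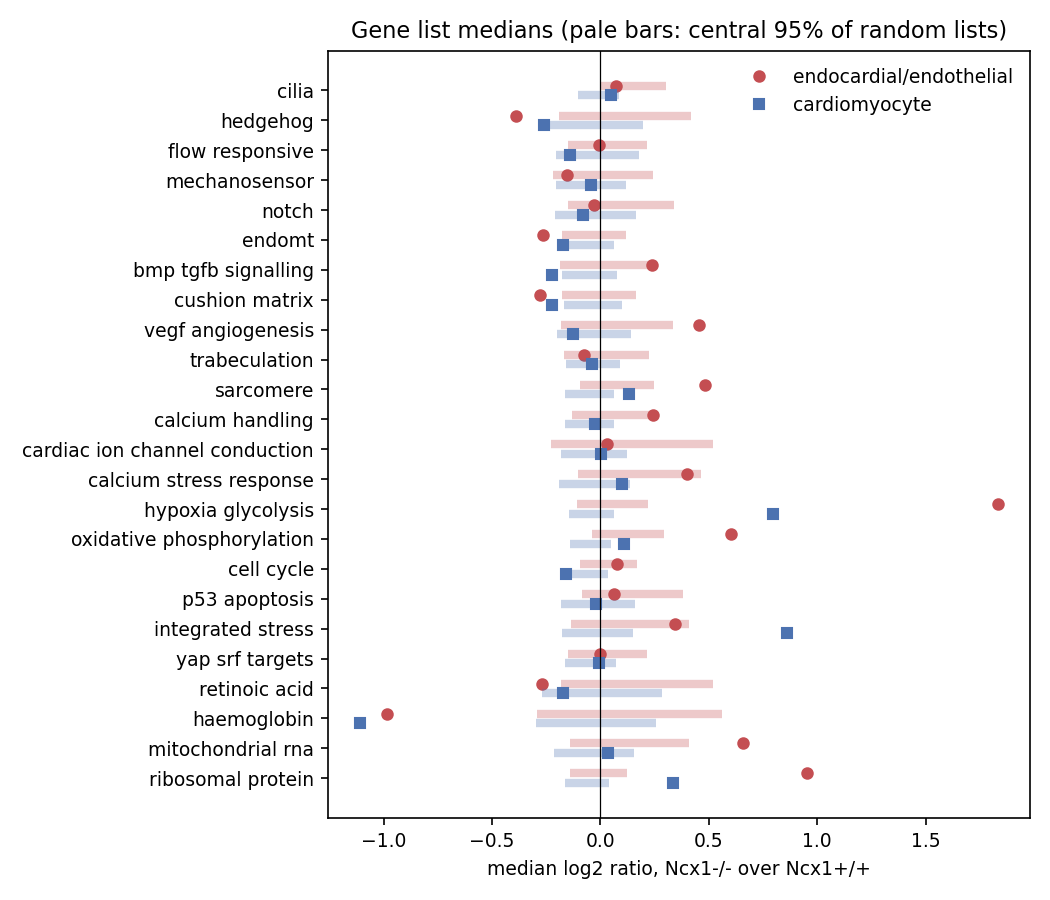
Median log2 ratio of Ncx1-/- over Ncx1+/+ for each gene list except the sex-linked list, in the endocardial class and in cardiomyocytes. There is 1 point per class, and pale bars show the central 95% of matched random lists. The endocardial hypoxia and glycolysis point lies furthest to the right, at 1.83, the integrated stress and hypoxia points of cardiomyocytes lie at 0.86 and 0.80, and the EndoMT and cushion matrix points of the endocardial class lie below 0, at -0.26 and -0.28.

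The heterozygous hearts were compared by the same rule. A gene whose Ncx1+/- level lies between those of Ncx1+/+ and Ncx1-/- cannot be called in Ncx1+/- by this rule. The counts therefore do not measure how close Ncx1+/- lies to Ncx1+/+. In the endocardial class 11 genes were higher and 21 lower in Ncx1+/- than in both others, and 58 and 161 in Ncx1+/+, beside 809 and 465 in Ncx1-/-. In the mesenchyme-type sub-clusters the counts were 6 and 15 for Ncx1+/-, and 73 and 86 for Ncx1+/+. In cardiomyocytes they were 24 and 18 for Ncx1+/-, and 60 and 120 for Ncx1+/+. In 50 simulated draws with no gene changed, the rule called 3 to 16 genes in Ncx1+/- in the endocardial class, 3 to 20 in the mesenchyme-type sub-clusters and 5 to 19 in cardiomyocytes, higher and lower together. The Ncx1+/- counts lie above these ranges, in the mesenchyme-type sub-clusters by 1 gene. Endocardial genes furthest above in Ncx1+/-, as ratios to Ncx1+/+, were Mdga2 (1.86, 1.47 to 2.36), Xaf1 (2.41), Nt5e, which encodes an ectonucleotidase (1.70), Jakmip2 (1.64) and Car13, a carbonic anhydrase gene (1.55). Furthest below were Hacl1 (2.10-fold), Ccsap (1.81-fold), Dancr (1.78-fold), Nme6 (1.74-fold) and Spsb3 (1.73-fold). In cardiomyocytes of Ncx1+/- the immediate early genes Fosb and Egr1 were 2.90- and 2.32-fold higher than in Ncx1+/+, and Adamts2, Clnk and Trp53i11 1.95-, 1.90- and 1.89-fold. The prolactin family genes Prl2c3 and Prl8a2 were 3.84- and 2.88-fold lower there, Smoc2, a matricellular protein gene, 2.99-fold, Nrsn2 2.56-fold and Fam163b 2.34-fold.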

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

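The tests of cytoplasmic RNA, of the outflow and canal regions, of the sub-cluster mix for cushion genes and of sub-clusters from thinned nuclei, and the values with cluster 17 counted in, were chosen only after the results were seen.

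Some genes stood apart in Ncx1-/- in opposite directions in endocardial nuclei and cardiomyocytes, 14 with named symbols. They were no more than independent lists would share: 12 were higher in endocardial nuclei and lower in cardiomyocytes against 15.003 for independent lists, and 5 the other way round against 7.04. In the same direction, 109 were higher in both classes against 12.8 and 77 lower against 8.27. The difference between the classes was not tested, since each rests on the same 1 library per genotype. Nrp2, a co-receptor for semaphorins and VEGF, had a log2 ratio to Ncx1+/+ of 0.72 in the endocardial class and -1.15 in cardiomyocytes. Bmp2, the myocardial signal for cushion formation, had 0.76 and -0.85. Its level in Ncx1+/+ was 7.34 CPM in the endocardial class against 84.2 CPM in cardiomyocytes. Free cardiomyocyte RNA may supply an unknown part of that endocardial level, so 0.76 is not an exact endocardial change. Tll1 stood at 139, 214 and 354 CPM in endocardial nuclei and at 19.9, 13.7 and 8.23 CPM in cardiomyocytes, and Pparg, a nuclear receptor of lipid metabolism, at 7.05, 7.09 and 16.7 CPM against 17.7, 14.97 and 8.73 CPM. Neat1, a noncoding RNA of nuclear paraspeckles, went the other way, at 30.9, 30.5 and 15.4 CPM against 6.90, 12.03 and 31.8 CPM.

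Hypoxia and glycolysis genes were higher in Ncx1-/- in the endocardial class, the mesenchyme-type sub-clusters and cardiomyocytes. The list median was smaller to Ncx1+/- than to Ncx1+/+, at 1.32 against 1.83 in the endocardial class and 0.57 against 0.80 in cardiomyocytes. Levels in Ncx1+/- thus tended to lie between those of the other libraries, and the pattern was not confined to Ncx1-/-. A different mix of endocardial sub-clusters was argued against, because the list median within the sub-clusters that held at least 50 nuclei of every library was 1.41 (1.11 to 1.83 over sub-clusters). More cytoplasmic RNA in the Ncx1-/- nuclei was argued against as the whole cause, because in cardiomyocytes the list median against Ncx1+/- exceeded that of ribosomal proteins by 0.59, although ribosomal proteins were higher in endocardial nuclei. The time between dissection and freezing stays open, since 1 pool per genotype was frozen. A lower oxygen supply without circulation may account for the pattern as a biological hypothesis, which these libraries cannot separate from handling of the pool.

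Mesenchyme-type nuclei were fewer in Ncx1-/- and 9 of 26 cushion matrix genes were lower, with 1 higher, in the endocardial class, but with unnamed cluster 17 counted as mesenchyme-type their share was 22.6% in Ncx1-/- against 22.1% in Ncx1+/+, and over that wider lineage Sox9, Col3a1, Tnc and Postn were 3.86-, 5.18-, 2.11- and 1.30-fold lower. Fewer UMIs per endocardial nucleus were argued against for the number of nuclei, since sub-clustering lineage nuclei thinned to 2000 UMIs, without cluster 17, gave a mesenchyme-type share of 23.4% in Ncx1+/+ and 10.1% in Ncx1-/-, a ratio of 2.31 (1.93 to 2.79), but for the genes the ratio of 3.94 for Sox9, Postn, Tnc and Vcan after thinning decides nothing, because levels scaled by the total do not shift with thinning. Loss of the whole outflow tract and atrioventricular canal was argued against, because cardiomyocyte clusters 5 and 8, which carry markers of these regions, held 17.1% of nuclei in Ncx1+/+ and 16.4% in Ncx1-/-, a ratio of 0.959, but loss of a part stays open, since cardiomyocyte cluster 6 fell from 8.56 to 3.65% and endocardial sub-cluster 6, with Isl1 among its leading genes, from 316 to 2 nuclei. Cardiomyocyte cluster 0, which carried as many of these region markers but was left out of that test, rose from 4.16 to 6.56%. Of the pooled clusters, cluster 5 fell from 7.18 to 6.27% and cluster 8 stood at 9.92 and 10.1%. A different mix of endocardial sub-clusters stays open for the lower cushion genes: within the sub-clusters that held at least 50 nuclei of every library, those 5 to 7 of the 9 lower members with enough counts had a median log2 ratio 0.378 of that of the same members in the whole class (0.314 to 0.966 over sub-clusters). A younger stage of the Ncx1-/- hearts stays open with 1 pool each, and so does reduced EndoMT without blood flow as the biological explanation. In cardiomyocytes the EndoMT and cushion matrix medians lay below 0 too, at -0.17 and -0.22. The lower list medians were thus not confined to the endocardial lineage.

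Erythroid nuclei were fewer in Ncx1-/-. Loss of erythroid nuclei to the filter on detected genes was argued against by haemoglobin counts over all deposited barcodes. As a share of the UMIs of these barcodes, haemoglobin UMIs were 3.25 times higher in Ncx1+/+ than in Ncx1-/-. The deposited barcodes held at least 500, 501 and 500 UMIs, so loss of smaller nuclei before deposit is not covered. Whether free haemoglobin RNA in cardiomyocyte nuclei came from the same blood cells was left undecided: the share of Hba-x among Hba-x and Hbb-y UMIs differed between the classes by up to 14.3 percentage points, between the bounds of 10 and 20 set beforehand. Blood lost or washed out when this pool was dissected stays open, with 1 pool per genotype. Fewer blood cells entering hearts without flow may also be a cause and was not tested.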

How the results depend on the processing

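Alternatives chosen only after seeing the data are the automatic Scrublet thresholds, all cardiomyocyte clusters, cardiomyocyte free RNA subtracted, the class without sub-cluster 12, sub-clustering without the genes standing apart in Ncx1-/-, the lineage as 1 class, cluster 17 counted as mesenchyme-type, and totals without Slc8a1 and Malat1. No paired analysis was possible because each genotype has 1 library and the result comes from no test. The epicardial comparison was not run under any setting. Of the values for single genes under all alternatives, 9812 stayed within the counting interval of the reported value, 828 moved and 25 reversed. Of the medians of lists not treated as leading, 828 stayed, 126 moved and 1 reversed. A change of sign counts as reversed only for a gene standing apart or a median outside the central 95% of random lists, so sign changes of smaller medians are not among these. In the endocardial class, 700 to 1252 of the 1274 genes standing apart in Ncx1-/- did so in the same direction under every alternative that keeps the threshold and count minimum, and 394 and 783 with a threshold of 2 times and a minimum of 300 counts. In cardiomyocytes 537 to 840 of 882 did so under the former, and in the mesenchyme-type sub-clusters 194 to 593 of 621, lowest at Leiden resolution 2.0, with 258 after thinning, 312 with cluster 17 and 317 with at least 1000 genes detected. Genes standing apart in opposite directions were seen only in the mesenchyme-type sub-clusters, 1 with the automatic Scrublet thresholds and 12 with cluster 17. The lineage and erythroid shares stayed lowest in Ncx1-/- under every alternative run on them, and so did the mesenchyme-type share except with cluster 17. Depth limits genes near 100 counts, and the mesenchyme-type sub-clusters of Ncx1-/- rest on 201 nuclei. Unless a sentence gives another reason, the cause of a moved value was not tested. Counts are given as higher and lower.

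With a threshold of 2 times, which calls fewer genes by construction, endocardial counts were 11 and 14 in Ncx1+/+, 1 and 1 in Ncx1+/-, and 194 and 200 in Ncx1-/-. Mesenchyme-type counts were 15 and 10, 0 and 1, and 70 and 110, and cardiomyocyte counts 8 and 38, 2 and 7, and 123 and 104. With at least 300 counts, which tests fewer genes, endocardial counts were 25 and 57 in Ncx1+/+, 3 and 2 in Ncx1+/-, and 450 higher in Ncx1-/-. Mesenchyme-type counts were 26 and 25, 2 and 0, and 98 and 185, and cardiomyocyte counts 9 and 55, 9 and 2, and 308 and 239. The cilia median was then -0.0133 and the integrated stress median in cardiomyocytes 0.73. With no count minimum, which tests more genes, endocardial counts were 88 higher in Ncx1+/+ and 38 and 35 in Ncx1+/-. Mesenchyme-type counts were 150 lower in Ncx1+/+, 20 and 29 in Ncx1+/-, and 527 higher in Ncx1-/-, and cardiomyocyte counts 97 higher in Ncx1+/+ and 59 and 34 in Ncx1+/-. The retinoic acid median in the endocardial class reversed to 0.12.

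At Leiden resolution 0.5 the mesenchyme-type share was 21.7% in Ncx1+/+ and 10.7% in Ncx1-/-, 57 mesenchyme-type genes were lower in Ncx1+/+, the hypoxia and glycolysis median in cardiomyocytes was 0.88, and Adamts9 in the mesenchyme-type sub-clusters reversed to -0.0449. At resolution 2.0 the mesenchyme-type share was 17.5, 13.0 and 3.41%. Endocardial genes lower in Ncx1+/- numbered 13 and the EndoMT median was -0.16. Mesenchyme-type counts were 27 and 46 in Ncx1+/+, 8 lower in Ncx1+/-, and 207 and 194 in Ncx1-/-, with a hypoxia and glycolysis median of 1.35. Log2 ratios there reversed for Tll1 (-0.68 to Ncx1+/+ and -0.81 to Ncx1+/-) and, against Ncx1+/-, for Klf2 (-0.16), Col9a1 (0.0665) and Nr2f2 (-0.15). With each gene scaled within its library before clustering, the hypoxia and glycolysis median was 1.74 in the endocardial and 1.80 in the mesenchyme-type nuclei. There 10 mesenchyme-type genes were higher in Ncx1+/- and 572 in Ncx1-/-, and Klf2 reversed to -0.00402.

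With at least 1000 genes detected, which removes small nuclei, the lineage share was 20.7% in Ncx1+/+ and 19.5% in Ncx1+/-, the erythroid share 3.53, 3.54 and 0.572%, and the mesenchyme-type share 14.9% in Ncx1+/- and 6.15% in Ncx1-/-. Mesenchyme-type counts were 46 and 54 in Ncx1+/+ and 11 higher in Ncx1+/-. There Col9a1 reversed to 0.0662 and, against Ncx1+/-, 0.24, and Top2a to -0.0950 and -0.0983. Without a doublet filter the lineage share was 18.1, 16.9 and 12.6%, the mesenchyme-type share 16.2, 13.3 and 8.54% and the erythroid share in Ncx1-/- 0.657%, and 11 mesenchyme-type genes were higher in Ncx1+/-, with a hypoxia and glycolysis median of 1.69. With the automatic Scrublet thresholds the lineage share was 20.7, 19.8 and 13.0%. Sub-clustering without the genes standing apart gave mesenchyme-type shares of 26.3 and 21.6% in Ncx1+/+ and Ncx1+/-.

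With TMM factors the endocardial medians were -0.0134 for cilia, -0.35 for EndoMT and 1.75 for hypoxia and glycolysis. With median-of-ratios size factors they were -0.0664 for cilia, -0.14 for flow-responsive genes, -0.40 for EndoMT, -0.42 for cushion matrix and 1.69 for hypoxia and glycolysis, and 489 endocardial genes were higher in Ncx1-/-. In the mesenchyme-type sub-clusters 211 genes were then higher, with a hypoxia and glycolysis median of 1.36. With thinned nuclei Slc8a1 in Ncx1-/- was 8.31% of Ncx1+/+, and 8.46% as mean CPM over nuclei, where 17 mesenchyme-type genes were higher in Ncx1+/-. Thinning gave 7 and 11 endocardial genes in Ncx1+/- and a cilia median of -0.0642. It gave 32 mesenchyme-type genes higher in Ncx1+/+, 7 lower in Ncx1+/- and 162 higher in Ncx1-/-, and 32 cardiomyocyte genes higher in Ncx1+/+ and 12 in Ncx1+/-. With cardiomyocyte free RNA subtracted the hypoxia and glycolysis median was 1.97 in endocardial and 1.70 in mesenchyme-type nuclei, Myh7 in endocardial nuclei reversed against Ncx1+/- to -0.27, 18 endocardial genes were higher in Ncx1+/-, and 10 and 23 mesenchyme-type genes stood apart there. The reversal of Myh7 decides nothing, because Myh7 is among the markers that set the amount subtracted. With all cardiomyocyte clusters the calcium handling and hypoxia medians were 0.0242 and 0.90. Without sub-cluster 12 the endocardial EndoMT and cushion matrix medians were -0.13 and -0.42.

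With cluster 17 counted as mesenchyme-type, which adds nuclei mostly of Ncx1-/-, the mesenchyme-type share was 22.1% in Ncx1+/+ and 22.6% in Ncx1-/-, and the lineage share 15.7% in Ncx1-/-. Mesenchyme-type counts were 156 lower in Ncx1+/+, 18 and 101 in Ncx1+/-, and 617 higher in Ncx1-/-, with a hypoxia and glycolysis median of 1.27. Log2 ratios to Ncx1+/+ and Ncx1+/- reversed for Pde3a (0.0178 and 0.47), Ryr2 (0.45 and 0.31), Cyr61 (0.69 and 0.85) and Rarb (0.66 and 0.51), and to Ncx1+/- for Tnc (0.60), Plxna4 (0.0501), Lef1 (0.18), Klf2 (-0.0518) and Tgfbr3 (-0.0401).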

Other observations

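No test in this part was chosen after its result was seen, and the values on cushion markers and sex-linked genes belong to no test.

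Over the whole endocardial lineage, cushion mesenchyme markers differed in size of effect. Postn, Col3a1 and Tnc were 7.28-, 6.47- and 6.11-fold lower in Ncx1-/- than in Ncx1+/+, and Sox9 and Papss2, a sulfate donor synthase gene of matrix synthesis, 3.66- and 3.12-fold. Cdh11, Twist1, Pdgfra and Msx1 were 1.99-, 1.71-, 1.63- and 1.54-fold lower. Prrx2 stood at 31.6, 30.02 and 25.3 CPM and the collagen gene Col1a2 at 36.4, 34.8 and 33.5 CPM. With unnamed cluster 17 added to the lineage, Postn, Col3a1, Tnc, Sox9 and Papss2 were 1.30-, 5.18-, 2.11-, 3.86- and 2.34-fold lower, Cdh11, Twist1, Pdgfra and Msx1 were 1.79-, 1.17-, 1.18- and 1.32-fold lower, while Col1a1 stood at 5.49, 10.8 and 18.1 CPM and Prrx1 at 4.78, 2.28 and 15.8 CPM. Within the endocardial class, hypoxia and glycolysis medians were 1.53 in sub-cluster 1, 1.11 in sub-cluster 2, 1.83 in sub-cluster 7 and 1.29 in sub-cluster 10, with 22 of 22, 27 of 27, 29 of 29 and 29 of 29 members above Ncx1+/+. In the same order, cushion matrix medians were -0.22, -0.02, -0.07 and -0.17 to Ncx1+/+ and -0.25, -0.15, 0.02 and 0.00 to Ncx1+/-. EndoMT medians were -0.19, -0.07, -0.25 and 0.01 to Ncx1+/+.

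Sex-linked transcripts differed between the pools. Over all kept nuclei Xist, the noncoding RNA of the inactive X chromosome, stood at 825, 975 and 1416 CPM. The Y-linked genes Uty, Eif2s3y, Ddx3y and Kdm5d stood at 203, 200 and 123, at 127, 133 and 74.9, at 47.5, 47.6 and 29.2, and at 29.7, 31.9 and 16.8 CPM. In the endocardial class 2 of the 6 genes of the sex-linked list were higher and 4 lower in Ncx1-/-, with a median log2 ratio of -0.93. The sex of the pooled embryos is not given in the sources used here. A different mix of sexes in the pools cannot be told apart from genotype, also for the X-linked genes Tmem255a, Pcdh11x and Pgk1 named above.

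A genomic region of another strain carried along with the targeted allele could place genes apart near Slc8a1. Within 10 Mb of the gene, 4 of 88 measured genes stood apart in Ncx1-/- in cardiomyocytes, 4.55% (exact binomial interval 1.25 to 11.2), against 6.53% of 13023 other autosomal genes, a ratio of 0.696. In the endocardial class 1 of 67 did, 1.49% (0.0378 to 8.04), against 11.9% of 10286, a ratio of 0.125. An excess of 2 times in both classes, the value set beforehand for this hypothesis, was not seen, although the interval in cardiomyocytes is wide.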
